A study of Mus musculus with 3 samples.

How the data were processed

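ATAC-seq was performed on cultured mouse HSCs treated with DMSO, AZD2014 or rapamycin, with 1 library per condition. Per the labels' protocols, 50000 cells were lysed and transposed for 30 min at 37 °C, and libraries were amplified by PCR and sequenced on an Illumina HiSeq 2500. How long the drugs were applied is not given in the sources used here. Per the submitters' processing notes, CASAVA was used and the genome build was mm10. The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled samples. Each line holds a chromosome, a start, an end, a peak name and a score. The peak names carry the word MACS, but the caller's version and settings, the aligner, the treatment of duplicates and mitochondrial reads, and any shift of reads for the transposase are not given in the sources used here. These steps set how many weak peaks are called and how wide they are.

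The deposited score is the authors' own value per peak, with a lowest value of 50.0 in each list. It was used only to rank and select peaks within a list, and scores of different lists are not on a shown common scale. Start positions in the deposited lists count from 0 and were written from 1 here. Read totals are unknown, so no signal was compared at shared peaks and no depth correction could be made. A peak absent from a list means only that it did not pass the authors' threshold there.

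Groups were taken from the sample titles. Before the data were examined, the comparisons, the alternatives, the gene lists and the rule for named genes were fixed. Peaks of 2 lists counted as shared when they overlapped by at least 1 bp, with 95% Wilson intervals on shares. Overlapping peaks of the 3 lists were merged into regions, each assigned to the lists with a peak in it. The overlap of both drugs' differences from DMSO was set beside the product of their numbers divided by all regions. It was also set beside 10000 random reassignments of the list names among regions found in 1 or 2 of the equal-length lists.

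Gene positions came from a table of RefSeq genes on GRCm38 patch 6, the assembly that mm10 names, with 21887 protein-coding genes. That table holds neither strand nor exons, so the planned promoter window around the transcription start was replaced by a gene end, 1 kb on either side of either end of a gene. Peaks were placed at a gene end, else in a gene body, else outside genes, and exons were not separated from introns. The planned motif search was not run because no genome sequence was used here. The gene window was the gene with 20 kb on either side.

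The 22 gene lists covered HSC transcription factors, HSC surface and niche genes, quiescence and CDK inhibitors, cell cycle, mTOR pathway, MAPK, MNK and CREB, immediate early, Myc and translation, autophagy and lysosome, integrated stress, glycolysis and lipid synthesis, mitochondria and oxidative stress, interferon response, apoptosis, myeloid, mast cell and basophil, erythroid, megakaryocyte, B cell, T cell, non-blood and housekeeping genes. Of 479 listed genes 477 were matched by symbol, Mx1 and Mx2 being the exceptions. For each list, the difference in genes with a gene-end peak and the ratio of window peaks were placed among 10000 random lists of the same size, matched on window peaks over the 3 lists. These percentiles describe the libraries and do not test the conditions.

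Named genes were, for each drug against DMSO, the 10 highest-scoring gene-end peaks found in one list and not the other, on each side and 1 per gene, without predicted genes named Gm or Rik. The 5 highest of each side were taken between the drugs. List members whose gene-end status differed from DMSO and 14 genes fixed in advance were added. Other genes and regions named were chosen after their values were seen.

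The alternatives were a reciprocal overlap of 50%, a distance of up to 500 bp, the 50% of each list with the highest scores, lists shortened to the 17189 highest-scoring peaks, peaks set to 200 bp, autosomes and X only, gene ends of 500 or 2500 bp, and gene windows of 50 kb or the gene body alone. The overlap code was tested on simulated data, an altered copy of the 17189 DMSO peaks, where all 200 removed and all 300 added peaks were found. With 300 random lists of 25 genes among 21887, 1.67% of gene-end percentiles and 6.67% of window percentiles fell outside the central 95% for AZD2014 against DMSO. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.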

Results

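Hematopoietic stem cells (HSCs) were sorted by flow cytometry from poly(I:C)-treated adult mice that carried floxed mTOR alleles but no Mx1-Cre transgene, so that mTOR was intact. The cells were cultured and exposed to the solvent DMSO, to 200 nM AZD2014 or to 1 µM rapamycin. AZD2014 (vistusertib) competes with ATP at the mTOR kinase, whereas rapamycin binds mTOR allosterically through FKBP proteins. Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, on 50000 cells per library. The series concerns how stem cells adapt to mTOR targeting, and the comparisons ask which accessible regions differ under each inhibitor. There was 1 library per condition and therefore no replicate check, so no difference below can be set against a spread between replicates and no p-value is given. Read numbers are not given in the sources used here, so depth is unknown, and intervals on shares are 95% Wilson intervals that cover counting error only.

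The DMSO list held 17189 peaks, the AZD2014 list 21321 and the rapamycin list 18233, which is 24.0% and 6.07% above DMSO. Peaks covered 11.7 Mb under DMSO, 16.8 Mb under AZD2014 and 14.3 Mb under rapamycin, with median widths of 610, 700 and 710 bp. Of the DMSO peaks, 88.9% (interval 88.4 to 89.3) overlapped an AZD2014 peak and 83.2% (82.6 to 83.7) a rapamycin peak. In the other direction, 70.9% (70.3 to 71.5) of AZD2014 peaks and 77.8% (77.2 to 78.4) of rapamycin peaks overlapped a DMSO peak. Sharing followed the authors' peak score. In the upper 50% of each list by score, between 98.0% and 99.9% of peaks had a partner in the full other list across the 6 directed pairs. In the lower 50% the shares were 43.9% to 77.9%.

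**Figure D1:**
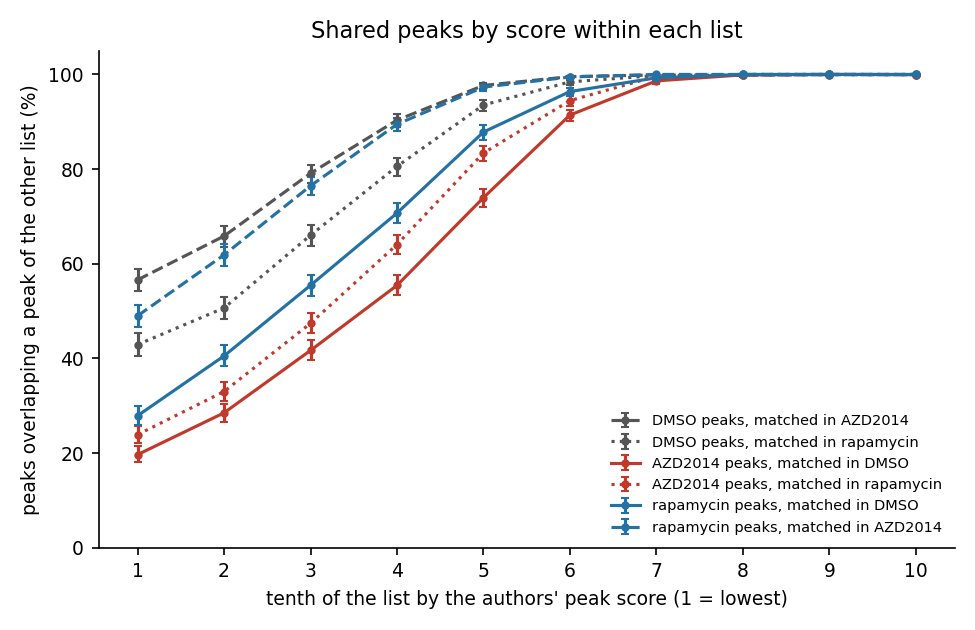
Percent of peaks in each list that overlap a peak of a second list (y axis), in 10 equal groups of the list ranked on the authors' peak score (x axis, 1 = lowest), for the 6 directed pairs of the DMSO, AZD2014 and rapamycin lists; bars are 95% Wilson intervals. Sharing is near complete in the highest groups of every pair, and the pairs separate in the lowest groups.

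Under AZD2014, 1014 of 21887 protein-coding genes had a peak within 1 kb of a gene end and none under DMSO, while 238 genes had one under DMSO and none under AZD2014. With all lists shortened to their 17189 highest-scoring peaks these numbers were 663 and 430. The 3 AZD2014 gene-end peaks with the highest scores and no DMSO partner lay at Zfp637, a zinc finger gene (chromosome 6, 117840873 to 117841757, mm10, score 258), Myadm, a myeloid-associated membrane protein gene (chromosome 7, 3289967 to 3290722, score 241), and Egln1, which encodes a prolyl hydroxylase that marks hypoxia-inducible factor for degradation (chromosome 8, 124949196 to 124949820, score 227). They were followed by Slc22a23, Phf21b, Enpp1, P3h3, Bend5, Ezh1 and Foxp1. Ezh1 encodes a Polycomb histone methyltransferase and Foxp1 a forkhead transcription factor, with scores of 192 and 191. The gene and its surroundings (20 kb on either side) held 2 peaks under DMSO and 6 under AZD2014 at Foxp1, and 2 and 3 at Ezh1. None of these 10 genes had any gene-end peak under DMSO, and all 10 peaks had a partner in the rapamycin list. Such a partner was the rule at these scores. It was present for 99.6% of all AZD2014 peaks scoring 182 to 252 and 100% of those scoring 252 to 342. The partners of these 10 peaks are therefore little evidence of a response common to both drugs.

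The DMSO gene-end peak with the highest score and no AZD2014 partner was at Mid1 (chromosome X, 169990967 to 169991820, score 260), a gene that spans the boundary of the mouse pseudoautosomal region. The others were at Pkig, Smpdl3a, Capn8, Map3k8, Zfp995, Eef1b2, Nrgn, Gng8 and Sox13. Map3k8 encodes a kinase upstream of MEK and ERK and Sox13 a SOX family transcription factor, with scores of 115 and 107. Of the 10 peaks, 6 had a partner under rapamycin, and Eef1b2, Nrgn and Gng8 kept a second gene-end peak under AZD2014. In all, 6200 AZD2014 peaks had no DMSO partner and 1913 DMSO peaks had no AZD2014 partner. With lists of one length, which makes the 2 numbers nearly equal by construction, they were 3049 and 2889.

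Of the 477 measured genes in the lists fixed beforehand, 319 had a gene-end peak under DMSO and 333 under AZD2014. There were 22 genes with a peak under AZD2014 alone of the pair and 8 under DMSO alone, and at equal list lengths 14 and 12. One of the former, the lipid synthesis regulator Srebf1, had an overlapping DMSO peak just outside the window, which leaves 21. Among 28 HSC transcription factor genes, Hoxa5, Hoxa7, Hoxa10 and Spi1 had a gene-end peak under AZD2014 and not under DMSO, and Gfi1b the reverse. The difference of 3 genes was 1 at equal list lengths. Peaks in the windows of these 28 genes numbered 86 under DMSO and 119 under AZD2014, a ratio of 1.38, against 1.03 to 1.29 for the central 95% of matched random lists (percentile 99.8). The ratio was 0.884 and the percentile 1.885 at equal list lengths, on the opposite side, and with the gene body alone the percentile was 78.9.

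Among 36 mTOR pathway genes, 29 had a gene-end peak under DMSO and 32 under AZD2014. The added genes were Tsc2, whose product restrains mTORC1 (chromosome 17, 24632286 to 24632979, score 164), Prr5, which encodes an mTORC2 subunit (score 52.6), and Grb10, an adaptor protein gene (score 84.8). Among 32 cell cycle genes, 29 had such a peak in each of the 2 lists, with Cdk6, a cyclin-dependent kinase gene, marked under AZD2014 alone (score 82.9) and Tyms, the thymidylate synthase gene, under DMSO alone (score 90.6). AZD2014 had 2 more of the cell cycle genes than DMSO in the upper 50% of lists by score, and the difference was 0 at equal list lengths. All 32 MAPK, MNK and CREB genes had a gene-end peak under DMSO and 31 under AZD2014, Creb5 being the exception (DMSO score 51.5). Among 23 immediate early genes the numbers were 20 and 22, with Fosl1 and Nr4a3 added. The difference was 0 with gene ends of 2500 bp and -1 in the upper 50% of lists by score. Among 23 interferon response genes they were 14 and 13. Rsad2 was marked under AZD2014 alone, and Ifitm1 and Irf7 under DMSO alone. The percentiles among random lists lay within the central 95% for each of these lists except the window peaks of the HSC transcription factors.

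**Figure D2:**
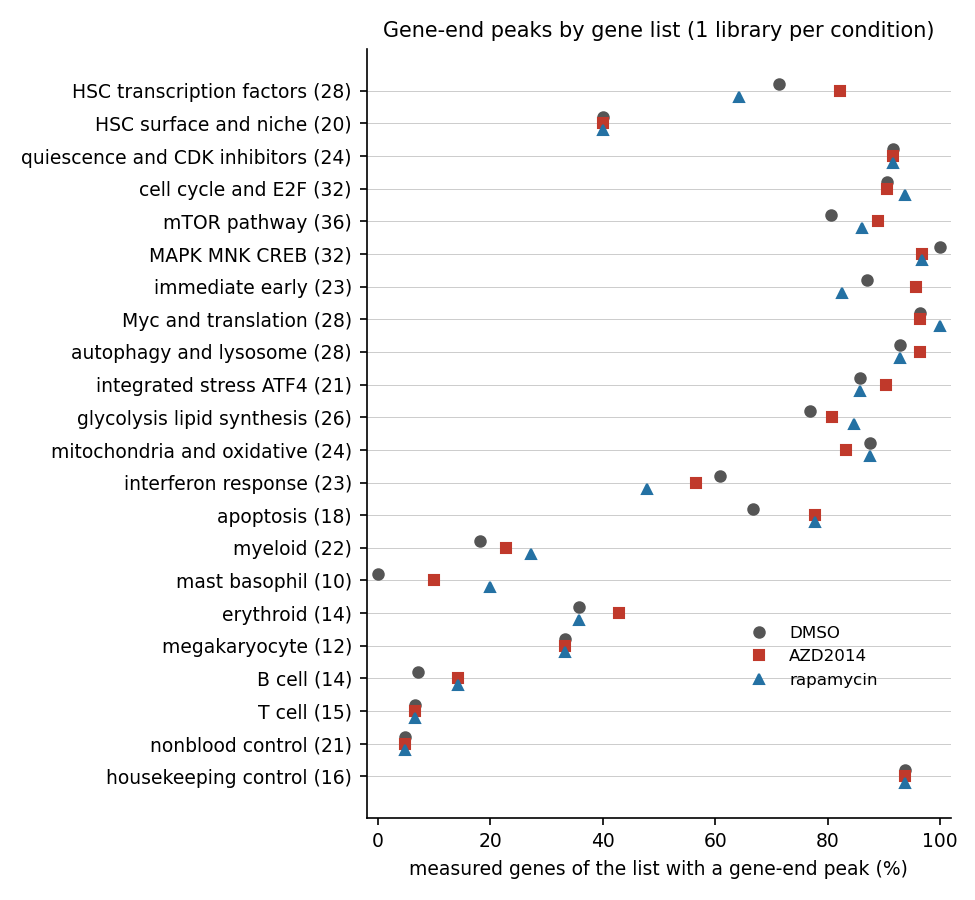
Percent of measured genes with a gene-end peak (x axis) for each of 22 gene lists (y axis, number of measured genes in brackets) in the DMSO, AZD2014 and rapamycin lists, 1 library each. The points of a list lie close together in most rows; the HSC transcription factors show 20, 23 and 18 of 28 genes, and the interferon response genes 14, 13 and 11 of 23.

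Under rapamycin, 668 protein-coding genes had a gene-end peak and none under DMSO, and 457 had one under DMSO and none under rapamycin. The rapamycin gene-end peaks with the highest scores and no DMSO partner were at Ctso, the cathepsin O gene (chromosome 3, 81932298 to 81933148, score 186), Eya1, which encodes a transcriptional coactivator with phosphatase activity (chromosome 1, 14309638 to 14310405, score 183), Egln1 (score 176) and Zfp637 (score 174). Auts2, Mrpl42, Elovl2, Nedd9, Mtap and Selenbp1 completed the 10. Elovl2 encodes a fatty acid elongase and Mtap an enzyme of methionine salvage. The window of Auts2 held 4 peaks under DMSO, 9 under AZD2014 and 7 under rapamycin. All 10 peaks had a partner in the AZD2014 list. So did 99.5% of all rapamycin peaks scoring 128 to 170 and 100% of those scoring 170 to 225.

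The DMSO gene-end peaks with no rapamycin partner were led by Mid1 again, followed by Oxld1, Nfkb1, Gpatch3, Klf12, Nr1h3, Ccdc97, Mlkl, Cyp4f17 and Pigv. Nfkb1 encodes an NF-kB subunit (chromosome 3, 135690813 to 135691890, score 138), Klf12 a Krüppel-like repressor (chromosome 14, 100284334 to 100285264, score 135), Nr1h3 a liver X receptor (score 130) and Mlkl the executor of necroptosis (score 124). Except for Mid1, all had a partner under AZD2014, and Gpatch3, Nr1h3, Ccdc97 and Pigv kept another gene-end peak under rapamycin. The window of Klf12 held 2 peaks under DMSO, 5 under AZD2014 and 0 under rapamycin. In all, 4046 rapamycin peaks lacked a DMSO partner and 2893 DMSO peaks lacked a rapamycin partner.

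Of the listed genes, 325 had a gene-end peak under rapamycin, with 16 marked under rapamycin and not DMSO and 10 the reverse, or 9 without Mknk1, whose rapamycin peak lay just outside the window. At equal list lengths the numbers were 12 and 11, and in the upper 50% of lists by score the direction turned, with 12 and 20. There, 257 listed genes had a gene-end peak under rapamycin and 265 under DMSO. Tsc2 (score 136), Prr5 and Spi1 had one under both drugs and not under DMSO, as did Eif2ak2, the gene of the double-stranded RNA-activated kinase PKR. So did Casp8, an initiator caspase gene, with scores of 50.6 under AZD2014 and 79.9 under rapamycin. Under rapamycin but neither AZD2014 nor DMSO, gene-end peaks were present at Mycl, Scd1, Bak1, Mpo, Ly6c2, Cpa3 and Ccnd3. Their scores were 68.9, 50.5, 69.5, 75.8, 50.1, 77.7 and 52.3, where the lowest score in the rapamycin list was 50. At Ccnd3 an AZD2014 peak overlapped the rapamycin peak from just outside the window. Among the HSC transcription factors, Lmo2, Prdm16 and Hoxa9 had a gene-end peak under DMSO and AZD2014 and not under rapamycin, leaving 18 of 28 against 20 under DMSO. With gene ends of 500 bp the direction turned, rapamycin having 2 genes more than DMSO. Trib3, a stress-induced pseudokinase gene, and Zfp36, an mRNA decay factor gene, showed the same arrangement. Mknk1, the gene of the kinase MNK1, was scored as lacking a gene-end peak under rapamycin only because of the window edge. Its rapamycin peak (chromosome 4, 115839039 to 115839570, score 328) overlapped both the DMSO and the AZD2014 peak.

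Interferon response genes had the lowest percentile of any list for gene-end peaks under rapamycin. Gene-end peaks were present at 14 of 23 genes under DMSO and 11 under rapamycin, the missing ones being Irf7, a transcription factor of the interferon response, Ifitm1 and Ifit2. This difference stood at percentile 0.89 of matched random lists, and at 0.09 with equal list lengths. In the upper 50% of the lists by score it was absent (percentile 37.1). The windows held 39 and 37 peaks, a ratio of 0.949. At Irf7 (chromosome 7, 141263183 to 141266499) the window held 2 peaks under DMSO and 0 under either drug, and its DMSO gene-end peak scored 61.3.

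Between the drugs, 5418 AZD2014 peaks had no rapamycin partner and 2305 rapamycin peaks had no AZD2014 partner, while 74.6% (interval 74.0 to 75.2) of AZD2014 and 87.4% (86.9 to 87.8) of rapamycin peaks were shared. The compounds were used at different doses, so these numbers do not compare them at matched exposure. With lists of one length, which makes these numbers nearly equal by construction, they were 2747 and 2704. The AZD2014 gene-end peaks with the highest scores and no rapamycin partner were at Bcdin3d, an RNA methyltransferase gene (chromosome 15, 99473585 to 99474956, score 194), Zfp410 (chromosome 12, 84316506 to 84317414, score 192), Rtl8b, Gtf2h4 and Reps2, and all 5 had a DMSO partner. On the rapamycin side they were at Fsd1l (chromosome 4, 53631138 to 53632140, score 160), Mdfic, Sptbn1, Slc25a24 and Thsd7a, of which all but Thsd7a had a DMSO partner. Gtf2h4 kept another gene-end peak under rapamycin and Sptbn1 under AZD2014.

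The HSC transcription factors had gene-end peaks at 23 genes under AZD2014 and 18 under rapamycin (percentile 99.7 of random lists), and 119 against 92 window peaks (percentile 99.3). The gene-end percentile was 28.0 with gene ends of 500 bp, 88.95 in the upper 50% of lists by score and 97.3 at equal list lengths. The difference of 5 genes was 0, 4 and 3 in these settings, in that order, and 4 with gene ends of 2500 bp. The window percentile was 88.1 with each peak of the gene list, though not of the random lists, counted once. It was 76.5 without Hoxa5, Hoxa7, Hoxa9 and Hoxa10, 54.8 with the gene body alone, 97.2 with 50 kb on either side and 0.675 at equal list lengths. Within the Hoxa cluster on chromosome 6, a developmental gene cluster active in HSCs, AZD2014 had 7 peaks and DMSO and rapamycin 4 each. These counts come from lists of unequal length and were not repeated at equal lengths. The peak near Hoxa4 was present in all 3 lists and had the highest score of the cluster in each, 168 under DMSO, 242 under AZD2014 and 151 under rapamycin. The AZD2014 peaks at Hoxa5 (52204292 to 52204813, score 85.0), Hoxa7 (52217345 to 52217961, score 55.4) and Hoxa10 (52240358 to 52240800, score 68.0) had no partner in either other list. All 3 stood in the lower 50% of the AZD2014 list by score. B cell genes held 15 window peaks under AZD2014 and 18 under rapamycin (percentile 0.945), which moved to 10.1 at equal list lengths, 6.41 with 50 kb on either side and 30.9 with the gene body alone.

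**Figure D3:**
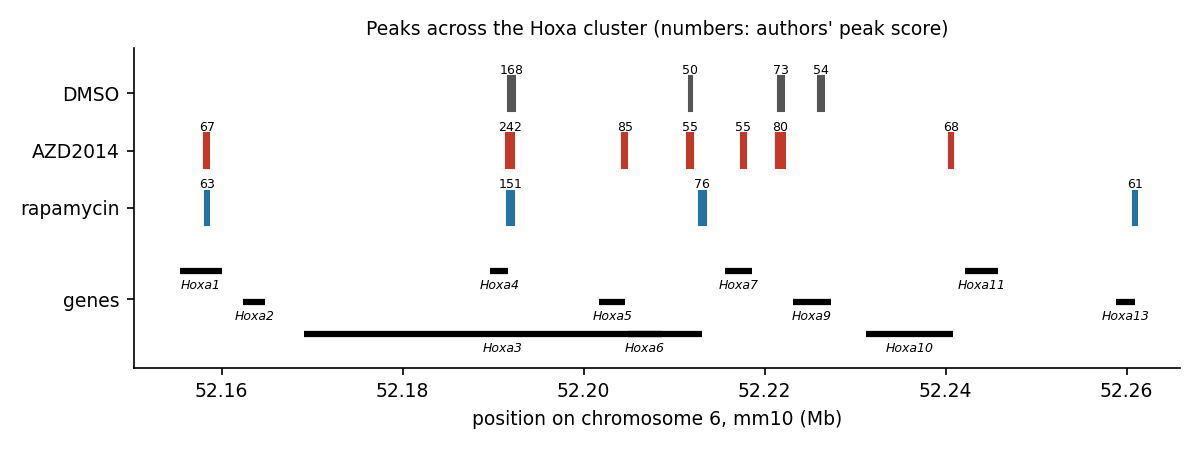
Peaks of the DMSO, AZD2014 and rapamycin lists across the Hoxa cluster on chromosome 6 (x axis, position in Mb, mm10), each drawn to scale with the authors' peak score above it, and gene extents below. AZD2014 has 7 peaks and DMSO and rapamycin 4 each, from lists of unequal length, and the peak near Hoxa4 is present in all 3.

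Merged across lists, the peaks formed 24981 regions. Of these, 13670 (54.7%) held a peak in all 3 lists and 61.4% (60.5 to 62.2) of those lay at a gene end. Regions under both drugs and not DMSO numbered 2155, those under AZD2014 and DMSO 1407, and those under rapamycin and DMSO 449. After shortening to equal lengths the drug pair still shared more regions without the third list (1377) than the other pairs (1079 and 820). Shuffling the list names among these regions gave 1092 per pair (central 95% 1040 to 1145). Regions under DMSO alone then numbered 2053, under rapamycin alone 1882 and under AZD2014 alone 1658, against 1864 (1794 to 1933) from shuffling. The shuffled ranges treat regions as independent and cover no spread between libraries. The shuffling also did not keep the list lengths equal, so the numbers of regions in pairs and in single lists are tied to each other.

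The regions that each drug added to the DMSO list overlapped. Of 6153 regions added under AZD2014 and 4008 under rapamycin, 2155 were the same. This is 2.18 times 987, the product of their numbers divided by all regions. Of 1898 and 2856 regions absent from each drug list and present under DMSO, 1449 were the same, against 217 (6.68 times). At equal list lengths the multiples were 3.05 and 5.0, and there the shuffled lists, which hold no effect, shared 1092 and 1864 regions where 1377 and 2053 were seen. These excesses are not separate results. With equal lengths, a DMSO list that shares fewer regions with each drug must hold more regions alone. The multiples do not measure a shared response. Added regions of either drug can lie only where DMSO had no peak, and absent ones only where it had a peak. Dividing by all regions ignores this and makes the product too small. Both comparisons also use the one DMSO library, which cannot be split, so part of either excess may come from it.

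**Figure D4:**
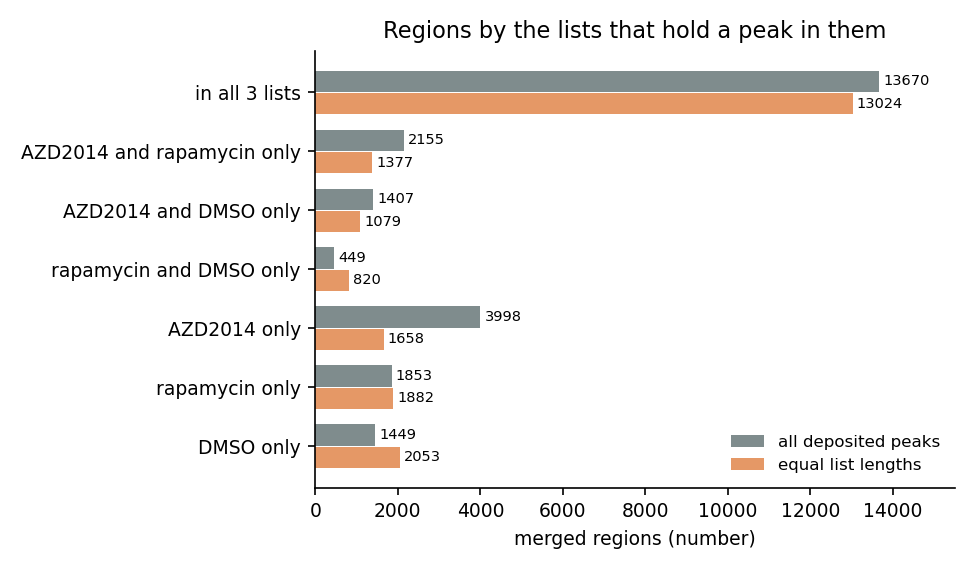
Number of merged regions (x axis) by the lists that hold a peak in them (y axis), for all deposited peaks and for equal list lengths of 17189 peaks. Regions in all 3 lists number 13670 and 13024, and regions under both drugs alone, 2155 and 1377, exceed either drug's pairing with DMSO.

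Several genes central to mTOR signalling and HSC biology were fixed for reporting whatever their values. Gene-end peaks were present in all 3 lists at Myc, Mtor, Rptor, Rictor, Mknk2, Creb1, Kit, Meis1, Cdkn1c and Ccnd2. Gata2 and Ccnd1 had none in any list, and Cdk6 had one under AZD2014 alone. The largest window differences were at Cdk6, with 3 peaks under DMSO, 7 under AZD2014 and 4 under rapamycin, and at Rptor, the gene of the mTORC1 subunit Raptor, with the same 3, 7 and 4. Ccnd2, a D-type cyclin gene, held 5, 3 and 4, and Ccnd1 2, 4 and 2. Mknk2, the MNK2 kinase gene, held 3, 5 and 4, Mtor 4, 3 and 3, Creb1 3, 2 and 2, and Meis1 5, 6 and 6. Kit held 1, 2 and 2, Gata2 3, 3 and 2, Myc 1, 1 and 2, and Mknk1, Rictor and Cdkn1c were equal across lists at 3, 2 and 1.

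The other gene lists are given with all peaks, and with the upper 50% of each list by score where that moved a difference from DMSO by more than 1 gene. The upper 50% held 8594 peaks under DMSO, 10660 under AZD2014 and 9116 under rapamycin, so it does not compare lists of one length. Quiescence and CDK inhibitor genes had gene-end peaks at 22 of 24 genes in every list, but in the upper 50% rapamycin differed from DMSO by -6 genes and AZD2014 from rapamycin by 7. HSC surface and niche genes had them at 8 of 20 in every list, with Cd34 marked only under AZD2014 and Itgb3 missing there. Given as DMSO, AZD2014 and rapamycin, the numbers were 27, 27 and 28 of 28 for Myc and translation genes, 26, 27 and 26 of 28 for autophagy and lysosome genes and 18, 19 and 18 of 21 for integrated stress genes. In the upper 50% by score, autophagy and lysosome genes with a peak were 5 more under AZD2014 and 4 more under rapamycin than under DMSO, and integrated stress genes 3 more under AZD2014. At equal list lengths these differences were 1, 0 and 1. With all peaks the numbers were 20, 21 and 22 of 26 for glycolysis and lipid synthesis genes, 21, 20 and 21 of 24 for mitochondrial and oxidative stress genes and 12, 14 and 14 of 18 for apoptosis genes, where Casp8 was joined by Bcl2a1b under AZD2014 and by Bak1 under rapamycin. For the apoptosis genes the AZD2014 difference from DMSO was 0 at equal list lengths and in the upper 50% by score, where that of rapamycin was -1. Rapamycin also turned to -1 there for the glycolysis and lipid synthesis genes. Hmox1, the heme oxygenase gene, was the one missing under AZD2014 among the mitochondrial and oxidative genes, and Hexa, a lysosomal enzyme gene, the one added among the autophagy genes. Housekeeping genes had peaks at 15 of 16 in every list.

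Markers of other blood cells, which a cultured sort could contain, were counted in the same way. Mast cell and basophil genes held 1 window peak under DMSO and 6 under each drug (percentiles 99.9 and 99.9). The drug peaks lay at Gzmb, Ms4a2, Cma1 and Il1rl1, and at Cpa3 under rapamycin. With the gene body alone the AZD2014 percentile was 22.7, with 50 kb on either side 97.3 and at equal list lengths 93.5, while rapamycin stood at 99.6 at equal lengths. Myeloid genes had gene-end peaks at 4, 5 and 6 of 22 genes, Cd68 being added under AZD2014 and Mpo and Ly6c2 under rapamycin, and in the upper 50% by score both differences from DMSO were 0. Erythroid genes had 5, 6 and 5 of 14 (Car1 added under AZD2014), megakaryocyte genes 4, 4 and 4 of 12 (but 2 more under AZD2014 and a difference of -1 under rapamycin in the upper 50% by score), B cell genes 1, 2 and 2 of 14 (Cd79a added under both drugs, with a difference of -1 for each at gene ends of 500 bp) and T cell genes 1, 1 and 1 of 15. Genes of non-blood tissues had 1, 1 and 1 of 21, at Apoa1 under DMSO and at Sftpc under each drug. Over all 22 lists, 132 percentiles were computed and 8 fell outside the central 95%, where the nominal rate gives 6.6. Random lists did not follow that rate, with 1.67% of gene-end and 6.67% of window percentiles outside for AZD2014 against DMSO. The percentiles also share libraries and genes, so 6.6 is no exact expectation.

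Peaks were concentrated at gene ends. A peak was present at 24.3% of gene ends under DMSO, 26.5% under AZD2014 and 24.9% under rapamycin, against 4.28%, 5.30% and 4.58% of windows moved 10 kb outward. The share of peaks at gene ends was 52.5% (interval 51.8 to 53.3) under DMSO, 46.0% (45.3 to 46.7) under AZD2014 and 50.3% (49.5 to 50.99) under rapamycin. The shares were 52.5%, 53.3% and 52.3% at equal list lengths. Peaks found under AZD2014 and not DMSO lay at gene ends in 17.9% of cases (16.9 to 18.8), inside gene bodies in 41.5% and outside genes in 40.6%. For peaks under rapamycin and not DMSO the gene-end share was 17.7% (16.5 to 18.9). DMSO peaks without an AZD2014 partner had a somewhat lower gene-end share, 15.0% (13.4 to 16.6). For those without a rapamycin partner it was 18.0% (16.7 to 19.5), close to the rapamycin share.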

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

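Alternatives chosen after the data were seen were equal lengths together with 200 bp peaks, counting each peak once, leaving out 4 Hoxa genes, matching the highest-scoring peaks of one list to equal numbers of another, and setting aside window-edge cases. Peaks were counted once in the gene list itself but not in its random lists. The others were fixed in advance, and the planned motif alternatives were not run. Of 466 recomputed values, 264 of them list differences, 363 stayed. This means within the interval, within 1.5 times the count, within 1 gene or on the same side of the central 95%. Of the main counts, shares and ratios, 92 stayed and 48 moved. Of the recomputed percentiles, 15 weakened to within the central 95% and 4 changed side. Equal lengths make the numbers of unmatched peaks nearly equal by construction. For the other moves the cause was not tested. Unknown depth limits every count, since weak peaks are those most dependent on it.

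With reciprocal overlap of 50%, shares were 82.59% of DMSO peaks in AZD2014, 78.81% of DMSO peaks in rapamycin and 85.25% of rapamycin peaks in AZD2014, and 2992 DMSO peaks lacked an AZD2014 partner. With a distance of 500 bp, 83.72% of DMSO peaks were shared with rapamycin. With peaks of 200 bp the 3 shares were 82.41%, 77.5% and 82.27%, 3023 DMSO peaks lacked an AZD2014 partner, and 713 regions were under rapamycin and DMSO only (1060 with equal lengths as well).

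With both lists cut to their upper 50% by score before matching, the 3 shares were 95.95%, 90.67% and 95.45%. Peaks without a partner numbered 2435 (AZD2014) and 348 (DMSO), 1338 (rapamycin) and 802 (DMSO), and 1968 (AZD2014) and 415 (rapamycin) for the 3 comparisons. Regions in all lists numbered 7661, under both drugs 1022, under AZD2014 and DMSO 557 and under rapamycin and DMSO 104. The added regions overlapped 3.564 times the product of their numbers divided by all regions. DMSO gene-end genes lacking one under AZD2014 numbered 140.

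At equal list lengths the 3 shares were 83.19%, 81.56% and 84.27%. AZD2014 and DMSO peaks without each other numbered 3049 and 2889, AZD2014 and rapamycin peaks without each other 2747 and 2704, regions under both drugs 1377 and under rapamycin and DMSO 820. Genes with a gene-end peak under AZD2014 and not DMSO numbered 663, and the reverse 430. The window peak ratio of AZD2014 to DMSO over all listed genes was 0.9914, against 1.18 with all peaks.

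The share of peaks at gene ends in DMSO, AZD2014 and rapamycin was 49.72%, 43.32% and 47.81% with 500 bp, 57.26%, 50.91% and 54.91% with 2500 bp, and 75.34%, 70.44% and 74.54% in the upper 50% by score. At equal lengths it was 53.31% for AZD2014 and 52.34% for rapamycin, so the lower AZD2014 share was absent there.

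The HSC transcription factor percentiles changed side. At equal lengths the window percentile was 1.885 for AZD2014 against DMSO and 0.675 against rapamycin, and with gene ends of 500 bp the gene-end percentile against rapamycin was 28.02. With gene bodies alone the window percentiles of these genes were 78.89 against DMSO and 54.81 against rapamycin, and the latter was 76.54 without the 4 Hoxa genes and 88.14 with each peak counted once. The mast cell and basophil window percentile for AZD2014 was 22.73 with gene bodies alone, and the gene-end percentile for rapamycin (98.5) was 50 in the upper 50% of lists and 96.32 at equal lengths. The interferon percentile under rapamycin ended with the upper 50% of lists (37.13) and was between 0.09 and 0.9 otherwise. In the upper 50% by score the rapamycin difference from DMSO was 0 for the mTOR pathway and the mast cell and basophil genes, against 2 with all peaks, and AZD2014 had 3 more mTOR pathway, 3 more megakaryocyte and 2 more cell cycle genes than rapamycin, and 1 more glycolysis and lipid synthesis gene. Of the 264 list differences, 230 stayed within 1 gene and 8 changed sign. In the upper 50% of lists, rapamycin differed from DMSO by -6 quiescence and CDK inhibitor genes, against 0 with all peaks. The named peaks had no partner within 500 bp either.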

Other observations

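The tests of peak score among AZD2014 peaks, of the highest-scoring peaks, of 200 bp peaks at equal lengths, of DMSO signal and of the Hoxa genes were chosen after the results were seen. Equal list lengths were planned, but their use to test longer drug lists was chosen afterwards, and the regions in the next 2 paragraphs were picked because of their scores.

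The strongest peaks that appeared under a drug and not under DMSO lay away from gene ends as well. The highest of all AZD2014 peaks without a DMSO partner was outside genes on chromosome 16 (91190946 to 91193931, mm10, score 577), 31.6 kb from Olig2, an oligodendrocyte lineage transcription factor gene, and also present under rapamycin. Another, 2330 bp wide, lay inside Jade1 (chromosome 3, 41563998 to 41566327, score 230), which encodes a histone acetyltransferase complex subunit, and was present under rapamycin too. Under rapamycin the highest peak without a DMSO partner was inside Mcph1 (chromosome 8, 18619021 to 18619586, score 191), a gene of chromosome condensation, also present under AZD2014. Between the drugs, the highest AZD2014 peak without a rapamycin partner was inside Trio (chromosome 15, 27871318 to 27872764, score 237), a guanine nucleotide exchange factor gene, and was present under DMSO.

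The highest-scoring DMSO peaks absent under both drugs were on chromosome 9 (3023123 to 3026111, score 388), 309 kb from the nearest gene, and on chromosome X beyond Mid1 (170008360 to 170010474, score 321), followed by the Mid1 gene-end peak (score 260). Another lay on the Y chromosome (90765251 to 90767005, score 123). Angpt1, the gene of angiopoietin 1, a niche factor for HSCs, had a DMSO peak 6.66 kb away (chromosome 15, 42683636 to 42684087, score 110) that was absent under both drugs, while the window of Angpt1 held 3 peaks under DMSO, 4 under AZD2014 and 2 under rapamycin. No list of artefact-prone regions was used here.

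AZD2014 had 6200 peaks without a DMSO partner against 1913 the other way. Of the former, 96.53% lay in the lower 50% of the AZD2014 list by score, but so did 97.7% to 99.6% of the unmatched peaks of the 5 other directed pairs, so this does not decide whether weak peaks near the calling threshold made the excess. In the upper 50% of each list, matched to the full other list, 215 AZD2014 peaks lacked a DMSO partner against 15 the other way. When the 8594 highest-scoring peaks of each list were matched to 17189 of the other, 34 lacked one on each side, a ratio of 1. A deeper or cleaner AZD2014 library and a broader opening of weak sites under the drug both remain open, since depth is unknown and there was 1 library per condition.

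The drug lists shared more regions with each other than either did with DMSO. Wider drug peaks as the whole cause were argued against by a ratio of 1.303 to the larger other pair with 200 bp peaks and equal lengths. Longer drug lists as the whole cause were argued against by a ratio of 1.276 at equal lengths. There the numbers were 1377 and 1079, against 2155 and 1407 with all peaks. The excess thus shrank at equal lengths, and list length may account for part of it. Among the 8594 highest-scoring peaks, 15 (AZD2014) and 14 (rapamycin) lacked a partner in the other drug's list, against 34 to 51 between either drug and DMSO. A shared response to mTOR inhibition is one hypothesis. A lower signal in the DMSO library cannot be told apart from it with 1 library per condition, so the pattern may come from either.

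HSC transcription factors held more window peaks under AZD2014 than matched genes did (percentile 99.8). Counting each peak of the gene list once, though not those of the random lists, left the percentile at 99.77. Leaving out Hoxa5, Hoxa7, Hoxa9 and Hoxa10 left it at 99.39. These values argue against the Hoxa cluster as the whole cause of the difference from DMSO. The difference from rapamycin, however, moved from 99.3 to 88.14 and 76.54 under these changes. Against DMSO the percentile was 78.89 with gene bodies alone and 1.885 at equal list lengths. The excess over matched genes was thus absent at equal list lengths, and a longer AZD2014 list is left open as its cause. How far list length alone would move the percentile was not tested, and neither was what turned the direction.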
